A study of Arabidopsis thaliana with 72 samples.

How the data were processed

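Gene expression was measured by RNA-seq in whole Arabidopsis thaliana seedlings of the accession Col-0 and of the double mutant phr1 phl1, which carries mutations in 2 related MYB transcription factors of the phosphate starvation response. Per the labels' protocols, seedlings germinated for 7 days on Johnson medium with 1 mM phosphate and 1% sucrose. They then spent 12 days on 1 mM phosphate (high Pi) or about 5 µM phosphate (low Pi), in a cycle of 9 h of light and 15 h of dark. During those 12 days they received no treatment, 10 µM methyl jasmonate (MeJA) or 1 µM flg22, a peptide of bacterial flagellin. Genotype, phosphate and treatment define 12 groups of 6 libraries, 72 in all. Each group holds 3 libraries of experiment A and 3 of experiment B, 2 separate experiments per the labels. The labels do not say that the libraries of an experiment come from separately grown cultures, so the p-values measure the spread between these samples, part of which may be technical.

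The libraries were prepared from 1000 ng of total RNA with poly(A) selection and without keeping strand, per the labels' protocols, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The submitters' processing notes name CASAVA 1.8, cutadapt 1.3, TopHat2 2.1.1, HTSeq 0.6.1p1 and the TAIR10 genome build, without roles or order. The authors deposited 1 table of raw read counts per gene, whole numbers with no normalization, for 27206 loci and 72 libraries. Every column matched 1 sample by its title. Gene symbols came from an annotation of the TAIR10.1 assembly, which gave a name to 26719 of the loci. It was used for names only. Counts of close paralogs, such as PDF1.2, PDF1.2b, PDF1.2c and PDF1.3, PHT1;1 and PHT1;2, or the transporter cluster AT2G04040 to AT2G04070, are uncertain, since reads shared between copies may have been split or dropped in the counting. Total counts ran from 692426 to 6883818 per library, with a median of 3785657.5, 4559964 in experiment A and 3581710.5 in experiment B. The group Col-0 high Pi MeJA was the shallowest, with a median of 1749954.5. No 2 libraries of a group differed by as little as sampling noise. The chi-square per degree of freedom over genes was at least 1.80 in the 180 pairs, with a median of 8.74.

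The counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 18583. Libraries were scaled by TMM, and 1 robust quasi-likelihood model over all 72 libraries held a term for each group and 1 for the experiment. The common biological coefficient of variation was 0.180. Each of 12 comparisons of 2 groups and 7 interactions was a contrast of that model. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with 0.05 as the threshold, and every adjusted p of a single gene is from edgeR unless another tool is named. Values after a log2 change are standard errors. Expression levels are CPM, counts scaled by the TMM-corrected library size, as mean ± SD over 6 libraries. Principal components were taken from the 1000 genes with the most variable log2 CPM, with a prior count of 2. Gene lists, 20 of them with 337 genes, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives, except those said to be added later. The lists cover phosphate starvation markers, phosphate transport and loading, membrane lipid remodelling, purple acid phosphatases, anthocyanin and flavonoid synthesis, jasmonate synthesis and signalling, jasmonate-responsive defence genes, aliphatic and indole glucosinolate synthesis, salicylic acid immunity, pattern-triggered immunity, camalexin synthesis, nuclear-encoded photosynthesis genes (a mark of green tissue), root hair cells, root endodermis and root tip, iron deficiency, ferritins, sulfur deficiency, senescence and cell division. They were tested with camera (limma 3.58.1, on log2 CPM) against all other genes, with a preset correlation of 0.01 between genes and again with the correlation estimated per list, and with fry. Adjusted p-values are over the 20 lists of a comparison. Where a call with the preset correlation was lost with the estimated one, that p is given, and the other camera calls printed held with both. A fold against a group with no counts is a lower bound against a floor of 3 counts over the group. Such a gene's fitted fold is no bound, and list medians in the text are also given with such members at their bound where that changed the value.

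The named genes are, for each comparison, up to 10 that rose and 10 that fell (5 and 5 for an interaction) with the largest log2 change among those past the threshold, with a mean log2 CPM of at least 1 and the same sign in both experiments. Added to these are up to 4 members of each list reported, those past the threshold with the largest change or else the 2 with the smallest p, and PHR1, PHL1 and FLS2. The text prints fewer than the rule allows and leaves out genes with 3 or fewer counts in a group.

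Simulated data with real gene means and library sizes tested the procedure. Of 200 genes changed under low Pi in Col-0 (18382 tested), 88% were called at a fold of 2 and 99% at 4. For its interaction with genotype (18372 tested) these shares were 71% and 95%. Each gave 8 false calls and called none of 19 unchanged lists. Real data, where 2767 genes of Col-0 differed in low Pi effect between experiments, may be harder to call and hold more false calls. Alternatives were the size factors of DESeq2, total counts alone, no filter, a mean of at least 10 counts, DESeq2 1.42.0, no experiment term, the replicate number as a block, only the groups of a comparison, each experiment alone, a stricter threshold and leaving out each replicate number in turn. In 1 library PHR1 and PHL1 levels went against its label. It stayed in the main model. Leaving it out, alone or with experiment B fitted alone, was added after the data were examined. The replicate numbers did not pair the samples, so no block entered the model. The raw reads were not used here.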

Results

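RNA-seq counts were collected from 72 libraries of whole Arabidopsis seedlings in 12 groups of 6. The groups combined 2 genotypes, 2 phosphate supplies and 3 treatments. Col-0 is the wild type, and phr1 phl1 carries mutations in PHR1 and PHL1, MYB transcription factors that bind promoters of phosphate starvation genes. Each group held 3 libraries of experiment A and 3 of experiment B. Col-0 high Pi MeJA was the shallowest group (692426 to 2403150 counts per library). The first principal component held 55.6% of the variance of the 1000 most variable genes. All 24 MeJA libraries lay between 44.5 and 51.1 on it, and 47 of the other 48 libraries between -30.2 and -18.4. The remaining library, labelled phr1 phl1 high Pi untreated B1, lay at 44.0.

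The targeted genes were examined first, with FLS2, the receptor kinase that binds flg22. In untreated Col-0, PHR1 (AT4G28610) stood at 61.3 ± 10.2 CPM at high Pi and 61.1 ± 5.22 CPM at low Pi (mean ± SD, n = 6). PHL1 (AT5G29000) stood at 12.7 ± 2.79 and 10.4 ± 1.83 CPM. With MeJA, PHR1 in Col-0 was at 62.7 ± 7.07 CPM at high Pi and 59.9 ± 5.96 at low Pi. With flg22 it was at 56.9 ± 5.47 and 68 ± 5.36. PHL1 in these 4 groups was at 15.7 ± 2.33, 13.3 ± 3.7, 12 ± 3.65 and 10.8 ± 3.45 CPM. In phr1 phl1, PHR1 was lower, at 35.2 ± 19.6 CPM at high Pi and 28.5 ± 7 at low Pi without treatment. It was at 22.4 ± 8.44 and 23.7 ± 5.62 with MeJA, and 24.8 ± 5.07 and 29.2 ± 11.4 with flg22. PHL1 reads were higher in the mutant than in Col-0, at 54 ± 22.9 and 75 ± 17.3 CPM without treatment. They were at 56 ± 24.1 and 56 ± 13.3 with MeJA, and 69.9 ± 6.46 and 90.2 ± 23.8 with flg22. In the untreated genotype comparisons PHR1 fell by 0.86 at high Pi and by 1.13 at low Pi on the log2 scale (adjusted p = 8.8e-04 and 1.9e-06). PHL1 rose by 2.08 ± 0.21 and 2.85 ± 0.22 (adjusted p = 2.8e-10 and 8.2e-16). These RNA levels do not show whether function is lost. FLS2 (AT5G46330) ranged from group means of 9.08 to 21.8 CPM.

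The library labelled phr1 phl1 high Pi untreated B1 went against its label. It held 68.6 CPM of PHR1, within the range of Col-0 (49.0 to 74.0 CPM) and above that of the other 35 phr1 phl1 libraries (12.9 to 44.5 CPM). Its PHL1 level of 20.3 CPM lay within the range of Col-0 (6.59 to 20.3 CPM) and below that of the other phr1 phl1 libraries (30.9 to 127 CPM). It also held 212 CPM of VSP2 and 818 CPM of PDF1.2, jasmonate-induced defence genes that reached at most 8.51 and 29.2 CPM in the other libraries without MeJA. Without it, PHR1 and PHL1 in phr1 phl1 high Pi untreated were at 28.6 ± 12.2 and 60.7 ± 17.8 CPM (n = 5), log2 changes of -1.11 and 2.26 against Col-0. Every comparison with untreated phr1 phl1 at high Pi draws on this library, and values without it are given beside the results it moved.

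**Figure D1:**
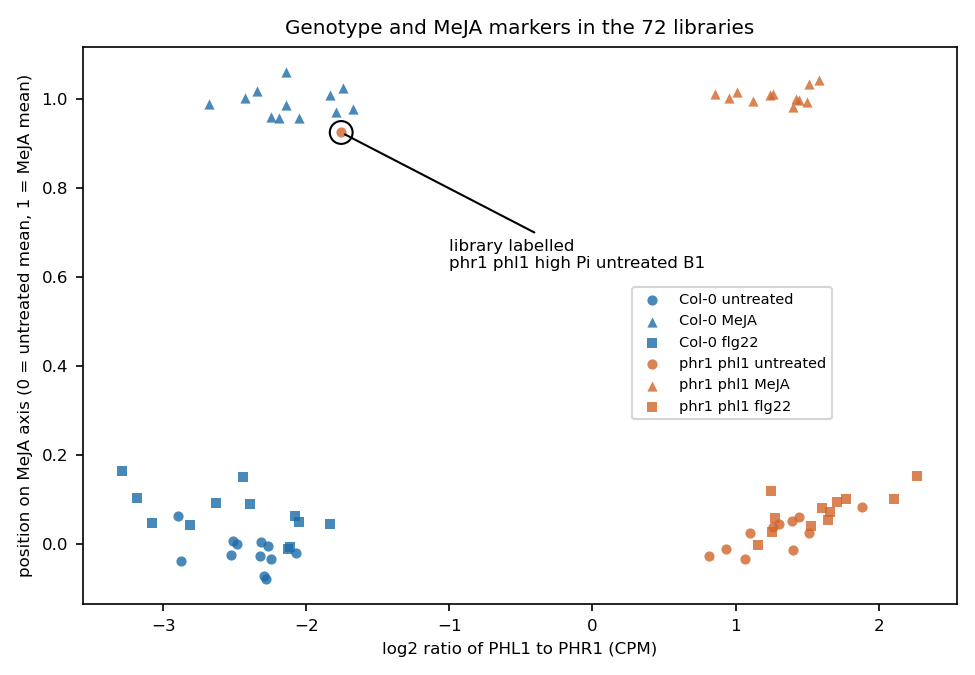
Each point is 1 of the 72 libraries, placed by its log2 ratio of PHL1 to PHR1 counts (horizontal) and its position on an axis of 859 MeJA-responsive genes, where 0 is the mean of the untreated groups and 1 that of the MeJA groups (vertical). The library labelled phr1 phl1 high Pi untreated B1, at -1.76 and 0.925, lies with the Col-0 libraries on the first axis and near the MeJA libraries on the other.

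Low Pi was compared with high Pi in untreated Col-0 to give the phosphate starvation response of the wild type. The non-coding RNAs IPS1 (AT3G09922, 6.59 ± 0.67) and AT4 (AT5G03545, 5.32 ± 0.49), which sequester a microRNA of the phosphate response, rose, as did the phosphate transporter PHT1;2 (AT5G43370, 4.65 ± 0.32). The phosphatases PECP1 (AT1G17710, 4.02 ± 0.53) and PPSPASE1 (AT1G73010, 2.96 ± 0.54) rose as well. So did the cation transporter OCT1 (AT1G73220, 3.38 ± 0.35) and the chlorophyll synthesis gene PORA (AT5G54190, 2.92 ± 0.54) (log2 change ± SE, n = 6 and 6, edgeR adjusted p at most 1.1e-04). AT4 went from 6.46 ± 3.81 CPM to 250.5 ± 109 CPM. The list of phosphate starvation markers had 11 of 12 members rise (11 adjusted over the list alone). The median was 2.75, with camera adjusted p = 1.7e-22 (medians of lists are of log2 changes). Phosphate transport and loading genes rose as a list (7 of 9 rose, 7 adjusted over the list alone, median 0.99, camera adjusted p = 1.4e-13). Among them were PHT1;9 (AT1G76430, 2.17 ± 0.36), PHT1;4 (AT2G38940, 1.88 ± 0.23) and PHT1;1 (AT5G43350, 1.14 ± 0.17). Membrane lipid remodelling genes, which replace phospholipids by other lipids, rose too (9 of 10 rose, 9 adjusted over the list alone, median 1.86, camera adjusted p = 4.8e-15). Examples were the glycerophosphodiesterases GDPD1 (AT3G02040, 2.48 ± 0.29) and GDPD2 (AT5G41080, 2.21 ± 0.38), the galactolipid synthase MGD3 (AT2G11810, 2.36 ± 0.47) and the phospholipase C NPC4 (AT3G03530, 2.03 ± 0.28) (adjusted p at most 3.8e-04). Purple acid phosphatases, secreted enzymes that release phosphate, rose as a list (4 of 6 rose, 4 adjusted over the list alone, median 1.25, camera adjusted p = 9.1e-08). They included PAP1 (AT1G13750, 1.72 ± 0.21), PAP12 (AT2G27190, 1.25 ± 0.12) and PAP17 (AT3G17790, 1.26 ± 0.41) (adjusted p at most 0.027).

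Root hair genes also rose in Col-0 at low Pi (12 of 14 rose, 13 adjusted over the list alone, median 0.99, camera adjusted p = 7.7e-12). Examples were RHS18 (AT5G22410, 1.60 ± 0.42) and RHS19 (AT5G67400, 1.195 ± 0.19) and the expansin EXPA18 (AT1G62980, 1.14 ± 0.23). Sulfur deficiency genes had lower counts (10 of 11 fell, 10 adjusted over the list alone, median -2.46, camera adjusted p = 1.7e-08, adjusted p = 0.065 with an estimated correlation). SDI1 (AT5G48850, -3.44 ± 0.77) and LSU2 (AT5G24660, -3.13 ± 0.53) and the sulfate-reducing enzymes APR2 (AT1G62180, -2.69 ± 0.45) and APR3 (AT4G21990, -2.52 ± 0.44) fell (adjusted p at most 0.0013). Iron deficiency genes were lower as well (13 of 18 fell, 16 adjusted over the list alone, median -1.43, camera adjusted p = 2.5e-09, adjusted p = 0.072 with an estimated correlation). The regulator BHLH100 (AT2G41240, -4.63 ± 1.47) and the signalling peptides IMA1 (AT1G47400, -3.20 ± 0.89) and IMA3 (AT2G30766, -3.13 ± 0.70) fell (adjusted p at most 0.025). Anthocyanin and flavonoid synthesis had 4 of 18 members fall (6 adjusted over the list alone). The median was -1.12, with camera adjusted p = 4.5e-04 (adjusted p = 0.46 with an estimated correlation). The pigment regulator MYB75 (AT1G56650, -3.22 ± 0.90) fell. Aliphatic glucosinolate synthesis had 6 of 19 members fall (8 adjusted over the list alone). The median was -0.48, with camera adjusted p = 0.0040 (adjusted p = 0.56 with an estimated correlation). Medians were -0.86 in experiment A and 0.10 in B. In all, 1254 genes rose and 1525 fell of 18583. Within experiment A alone 3145 rose and 3245 fell, and within experiment B alone 63 and 21. Phosphate starvation markers had medians of 2.52 and 3.79 in experiments A and B. Those of sulfur deficiency genes were -3.39 and -0.80, and of iron deficiency genes -2.06 and -0.55.

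The same comparison in untreated phr1 phl1 asked how much of that response remained in the mutant. Phosphate starvation genes rose, with AT4 (3.30 ± 0.46), PPSPASE1 (2.59 ± 0.63) and PECP1 (2.19 ± 0.65) and the inhibitor of PHR proteins SPX1 (AT5G20150, 2.56 ± 0.34) (adjusted p at most 0.018). The markers had 6 of 12 members rise (8 adjusted over the list alone). The median was 1.92, with camera adjusted p = 3.1e-09. Without the doubted library the median was 1.74. Lipid remodelling rose (7 of 10 rose, 9 adjusted over the list alone, median 1.73, camera adjusted p = 2.4e-16). It included GDPD1 (3.26 ± 0.30), MGD2 (AT5G20410, 2.17 ± 0.28) and GDPD2 (2.103 ± 0.38) and the phospholipase D PLDP2 (AT3G05630, 2.09 ± 0.33). Purple acid phosphatases rose too (4 of 6 rose, 4 adjusted over the list alone, median 1.56, camera adjusted p = 1.8e-08), among them PAP1 (2.02 ± 0.21), PAP17 (1.93 ± 0.42) and PAP12 (1.196 ± 0.12). Phosphate transport rose as a list (5 of 9 rose and 1 fell, 5 up and 1 down adjusted over the list alone, median 0.36, camera adjusted p = 8.0e-05). Without that library the median was 0.36, with camera adjusted p = 1.5e-04 (0.053 with an estimated correlation). PHT1;2 (2.17 ± 0.47) and PHT1;4 (1.41 ± 0.24), the ubiquitin conjugase PHO2 (AT2G33770, 0.97 ± 0.16) and the transporter traffic factor PHF1 (AT3G52190, 0.73 ± 0.17) were its examples (adjusted p at most 0.0023). Immune genes of the salicylic acid pathway rose in the mutant (14 of 22 rose, 17 adjusted over the list alone, median 1.08, camera adjusted p = 3.8e-11). The pathogenesis-related gene PR1 (AT2G14610, 5.19 ± 0.70) went from 4.67 ± 8.04 CPM to 218 ± 115 CPM. PBS3 (AT5G13320, 2.98 ± 0.67) and FMO1 (AT1G19250, 2.79 ± 0.69) rose, with the pathogen-responsive genes PCC1 (AT3G22231, 6.72 ± 1.05), LURP1 (AT2G14560, 6.04 ± 0.97) and ANK (AT5G54610, 5.19 ± 0.84) and the chaperone BIP3 (AT1G09080, 4.97 ± 0.80) (adjusted p at most 0.0038).

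Aliphatic glucosinolate genes fell in phr1 phl1 at low Pi (16 of 19 fell, 19 adjusted over the list alone, median -0.90, camera adjusted p = 8.4e-16). Among them were CYP79F1 (AT1G16410, -1.35 ± 0.35), CYP79F2 (AT1G16400, -1.33 ± 0.24) and FMOGS-OX1 (AT1G65860, -1.65 ± 0.36). Without the doubted library the median was -0.66, with camera adjusted p = 1.0e-09 (0.13 with an estimated correlation). In experiment B alone without it CYP79F1 and CYP79F2 turned to 0.30 and 0.051. Sulfur deficiency genes were lower (10 of 11 fell, 10 adjusted over the list alone, median -1.93, camera adjusted p = 7.3e-09, adjusted p = 0.050 with an estimated correlation). These included SDI1 (-4.62 ± 0.88), LSU2 (-2.25 ± 0.53), SDI2 (AT1G04770, -2.12 ± 0.49) and APR1 (AT4G04610, -2.08 ± 0.47). Anthocyanin genes were lower too (13 of 18 fell, 16 adjusted over the list alone, median -1.88, camera adjusted p = 2.6e-11, adjusted p = 0.092 with an estimated correlation). DFR (AT5G42800, -3.79 ± 0.76) and TT8 (AT4G09820, -3.33 ± 0.84) fell (adjusted p at most 0.0048), with DFR at -2.43 without that library (adjusted p = 0.020). Jasmonate-responsive defence genes had 1 of 19 members rise and 10 fall (1 up and 13 down adjusted over the list alone). The median was -2.76, with camera adjusted p = 0.011 (adjusted p = 0.45 with an estimated correlation). PDF1.2 (AT5G44420, -5.57 ± 0.97) and VSP2 (AT5G24770, -4.96 ± 0.92) were lower at low Pi. Without that library the list's median was -0.01, with camera adjusted p = 0.90. The changes of PDF1.2 and VSP2 were -0.79 and -0.11 (adjusted p = 0.52 and 0.95). Altogether 1188 genes rose and 1092 fell, and 1244 and 1052 without that library. Experiment A alone gave 2711 and 2517. Experiment B alone gave 250 and 179, and 119 and 16 without that library. Genes that rose in both genotypes numbered 457 (80.2 by chance for independent lists), and 486 fell in both (89.6 by chance). Their control libraries were different.

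The interaction tested whether the low Pi response differed between the genotypes. The response of root hair genes was lower in phr1 phl1 than in Col-0 (5 of 14 fell, 12 adjusted over the list alone, median -1.21, camera adjusted p = 1.2e-21). Examples were RHS19 (-1.51 ± 0.27) and PRP3 (AT3G62680, -1.51 ± 0.30) (mutant minus Col-0, log2). IPS1 (-5.43 ± 1.04) and the phospholipase NPC4 (-2.44 ± 0.42) responded less in the mutant (adjusted p = 0.0019 and 3.2e-04). Phosphate starvation markers as a list were lower (1 of 12 fell, 4 adjusted over the list alone, median -1.13, camera adjusted p = 2.0e-06, adjusted p = 0.060 with an estimated correlation). So were transport genes (1 of 9 rose and 2 fell, 1 up and 4 down adjusted over the list alone, median -0.50, camera adjusted p = 4.2e-04, adjusted p = 0.060 with an estimated correlation). Within the transport list PHO2 (1.13 ± 0.23) was higher in the mutant and PHT1;1 (-0.99 ± 0.23) lower. Lipid remodelling did not pass (1 of 10 fell, 1 up and 1 down adjusted over the list alone, median -7.0e-04, camera adjusted p = 0.97). Its median and mean lay below 0 while the test pointed up. Salicylic acid genes responded more in the mutant (2 of 22 rose, 13 adjusted over the list alone, median 0.67, camera adjusted p = 1.0e-09, adjusted p = 0.060 with an estimated correlation), PBS3 (4.21 ± 0.99) among them. So did the camalexin enzyme PAD3 (AT3G26830, 2.56 ± 0.60) and, outside these lists, PCC1 (7.97 ± 1.65) and ANK (6.42 ± 1.41) (adjusted p at most 0.018). Without the doubted library, the estimated correlation gave adjusted p = 0.023 for the markers and 0.081 for transport. It gave 0.030 for salicylic acid genes and 0.0084 for root hair genes. Of salicylic acid genes 1 then rose, and 1 transport and 3 root hair genes fell. Jasmonate defence genes (1 of 19 fell, 6 adjusted over the list alone, median -2.57, camera adjusted p = 1.0e-05, adjusted p = 0.23 with an estimated correlation) had a median of -0.23 without it (camera adjusted p = 0.29). The jasmonate synthesis gene AOC2 (AT3G25770, -3.76 ± 0.96) then changed by -0.61 (adjusted p = 0.92). There were 81 genes with a higher and 78 with a lower response in the mutant, and 63 and 34 without it. Experiment A alone gave 204 and 243, and experiment B alone 1 and 0.

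The genotypes were compared directly without treatment. At low Pi, phosphate transport genes were lower in phr1 phl1 than in Col-0 (1 of 9 rose and 6 fell, 1 up and 7 down adjusted over the list alone, median -0.99, camera adjusted p = 1.2e-11). PHT1;2 (-3.82 ± 0.30), PHT1;9 (-2.56 ± 0.38) and PHT1;1 (-1.35 ± 0.17) were lower and PHO2 (1.99 ± 0.16) higher (adjusted p at most 2.1e-06). Phosphate starvation markers were lower (7 of 12 fell, 9 adjusted over the list alone, median -1.58, camera adjusted p = 5.8e-12), among them SPX3 (AT2G45130, -3.77 ± 0.49), IPS1 (-2.99 ± 0.45) and PECP1 (-2.47 ± 0.46). So were the lipase NPC4 (-2.52 ± 0.29), OCT1 (-4.55 ± 0.39) and the phosphatase PAP10 (AT2G16430, -1.55 ± 0.23) (adjusted p at most 1.9e-04). Lipid remodelling genes did not pass as a list (1 of 10 rose and 1 fell, 1 up and 1 down adjusted over the list alone, median -0.16, camera adjusted p = 0.53). The median was -0.26 in experiment A and 0.21 in B alone (camera adjusted p = 0.015 and 0.0020). MGD2 (0.89 ± 0.26) was higher. Root hair genes were lower (9 of 14 fell, 12 adjusted over the list alone, median -0.98, camera adjusted p = 2.2e-22). They included RHS19 (-1.39 ± 0.19) and PRP3 (-1.26 ± 0.21). Endodermis and root tip genes were lower (1 of 12 fell, 2 adjusted over the list alone, median -0.32, camera adjusted p = 2.4e-04), among them the Casparian strip gene CASP4 (AT5G06200, -1.03 ± 0.28). Photosynthesis genes, a mark of green tissue, had lower counts too (6 of 28 fell, 20 adjusted over the list alone, median -0.35, camera adjusted p = 2.5e-16, adjusted p = 0.070 with an estimated correlation). Among them were the carboxylase subunit RBCS3B (AT5G38410, -0.61 ± 0.14) and carbonic anhydrase CA1 (AT3G01500, -0.58 ± 0.15). Salicylic acid genes were higher in the mutant (9 of 22 rose, 11 adjusted over the list alone, median 0.67, camera adjusted p = 1.9e-13). These included PR1 (5.79 ± 0.74), FMO1 (2.94 ± 0.69), PBS3 (2.68 ± 0.65) and WRKY70 (AT3G56400, 2.11 ± 0.47). Camalexin synthesis genes, which make an antimicrobial indole compound, were higher (3 of 7 rose, 3 adjusted over the list alone, median 0.81, camera adjusted p = 1.1e-06). Examples were CYP71A12 (AT2G30750, 2.62 ± 0.58), PAD3 (2.37 ± 0.41) and GSTF6 (AT1G02930, 2.35 ± 0.44) (adjusted p at most 0.0060). Pattern-triggered immunity genes had 2 of 29 members rise (9 adjusted over the list alone). The median was 0.34, with camera adjusted p = 6.6e-06 (adjusted p = 0.070 with an estimated correlation). The receptor kinase EFR (AT5G20480, 1.43 ± 0.27) was higher. The senescence gene SAG13 (AT2G29350, 6.62 ± 0.88) and the transporter gene AT2G04050 (6.19 ± 0.61) were higher too. The totals were 405 higher and 237 lower genes. They were 613 and 444 in experiment A alone, 70 and 26 in experiment B alone, and 623 and 169 with scaling to total counts.

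At high Pi the acid phosphatase PAP10 (-1.44 ± 0.22), the plastid desaturase FAD7 (AT3G11170, -0.58 ± 0.10) and the glycosyltransferase family gene AT2G41640 (-0.89 ± 0.19) were lower in untreated phr1 phl1 than in Col-0. PHO2 (0.86 ± 0.16) was higher (adjusted p at most 0.0048). These 4 genes kept their calls without the doubted library. Their log2 changes were then -1.73, -0.55, -0.91 and 1.01 (adjusted p at most 0.047). Photosynthesis genes were lower (2 of 28 fell, 13 adjusted over the list alone, median -0.30, camera adjusted p = 1.0e-18, adjusted p = 0.11 with an estimated correlation). They included CA1 (-0.57 ± 0.15) and rubisco activase RCA (AT2G39730, -0.54 ± 0.14). Without that library these were -0.51 and -0.48 (adjusted p = 0.40 and 0.37) with 3 members lower over the list alone. The list's median was -0.28, with camera adjusted p = 3.5e-18 (0.18 with an estimated correlation). With that library in the group, jasmonate genes were higher in the mutant. Defence genes had 12 of 19 members rise (16 adjusted over the list alone). The median was 3.22, with camera adjusted p = 3.1e-11 (adjusted p = 0.11 with an estimated correlation) (median 2.36 with members that had no counts in a group at their bound). Among them were PDF1.2 (6.54 ± 1.06), PDF1.3 (AT2G26010, 6.14 ± 1.09) and PDF1.2c (AT5G44430, 6.28 ± 1.06). Synthesis and signalling genes had 14 of 37 members rise (20 up and 1 down adjusted over the list alone). The median was 0.68, with camera adjusted p = 6.1e-15 (adjusted p = 0.11 with an estimated correlation). These included JOX3 (AT3G55970, 6.32 ± 1.08), AOC2 (3.48 ± 0.66) and JAZ5 (AT1G17380, 3.38 ± 0.61). Without it, 0 of the 19 defence genes and 0 of the 37 synthesis genes passed in edgeR. The medians were then 0.33 and 0.20, with camera adjusted p = 0.0067 and 0.0017 (0.30 for each with an estimated correlation). PDF1.2 and JOX3 changed by 1.71 and 1.04. The lowest adjusted p of the 6 jasmonate genes named was then 0.26. The count of 170 higher and 48 lower genes became 8 and 4 without it, and 246 and 26 with it and scaling to total counts. A model of these 2 groups only turned the majority, with 18 higher and 54 lower. Experiment A alone, which does not hold that library, gave 162 and 70. Experiment B alone gave 116 and 63, and 3 and 2 without it.

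**Figure D2:**
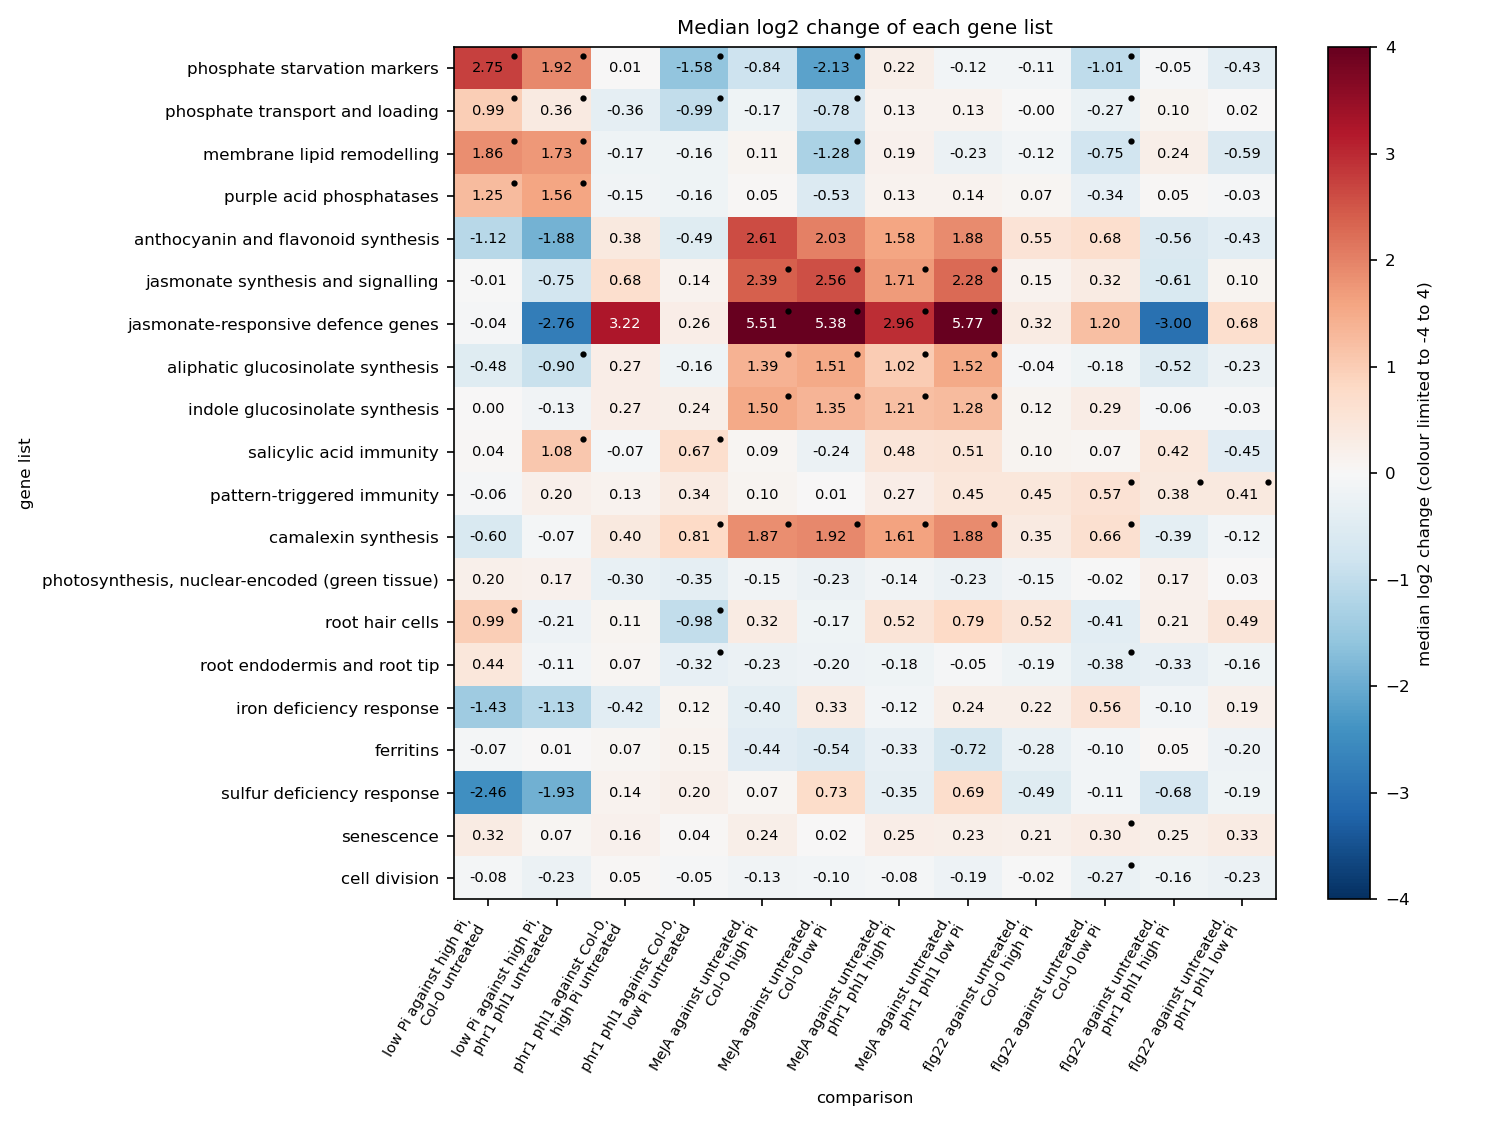
Median log2 change of each of the 20 gene lists (vertical) in the 12 comparisons of 2 groups (horizontal), as colour from -4 to 4 with the value printed. A dot marks lists past 0.05 in camera with both the preset and the estimated correlation. Phosphate starvation markers stand at 2.75 for low Pi in Col-0 and at -2.13 for MeJA at low Pi in Col-0, and jasmonate-responsive defence genes at 5.51 for MeJA in Col-0 at high Pi. Without the library labelled phr1 phl1 high Pi untreated B1 their values of -2.76, 3.22, 2.96 and -3.00 were -0.01, 0.33, 5.78 and 0.11, and other values of these 4 comparisons draw on that library too.

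MeJA was compared with no treatment to give the jasmonate response at each phosphate supply. In Col-0 at high Pi, jasmonate-responsive defence genes rose (17 of 19 rose, 18 adjusted over the list alone, median 5.51, camera adjusted p = 1.6e-32). The defensins PDF1.2 (10.10 ± 1.09), PDF1.2c (9.94 ± 1.05) and PDF1.3 (9.61 ± 1.099), which are close paralogs, and the lectin JAL23 (AT2G39330, 9.50 ± 0.99) were the examples (adjusted p at most 2.5e-10). PDF1.2 went from 1.06 ± 0.823 CPM to 1132 ± 392 CPM. Jasmonate synthesis and signalling genes rose (32 of 37 rose and 1 fell, 32 up and 1 down adjusted over the list alone, median 2.39, camera adjusted p = 9.7e-66). They included the hydroxylase JOX3 (9.39 ± 1.03), the repressor JAZ5 (5.63 ± 0.54), and the synthesis enzymes AOC2 (6.56 ± 0.68) and LOX2 (AT3G45140, 5.51 ± 0.57). Aliphatic glucosinolate genes rose (17 of 19 rose, 19 adjusted over the list alone, median 1.39, camera adjusted p = 2.5e-34), among them BCAT4 (AT3G19710, 2.42 ± 0.27) and MYB76 (AT5G07700, 2.29 ± 0.36). So did indole glucosinolate genes (13 of 16 rose, 13 adjusted over the list alone, median 1.505, camera adjusted p = 2.0e-31). Examples were IGMT1 (AT1G21100, 3.93 ± 0.51), ASA1 (AT5G05730, 2.33 ± 0.23) and CYP79B2 (AT4G39950, 2.30 ± 0.22). Camalexin genes rose (4 of 7 rose, 4 adjusted over the list alone, median 1.87, camera adjusted p = 3.6e-10). Among them were GSTF6 (2.19 ± 0.44) and GGP1 (AT4G30530, 1.87 ± 0.20) (adjusted p at most 1.8e-04). Anthocyanin synthesis had 13 of 18 members rise (13 adjusted over the list alone). The median was 2.61, with camera adjusted p = 3.3e-10 (adjusted p = 0.16 with an estimated correlation). DFR (4.54 ± 0.64), UGT79B1 (AT5G54060, 4.37 ± 0.65) and LDOX (AT4G22880, 4.04 ± 0.61) rose. Genes that fell included the growth regulator GASA5 (AT3G02885, -3.37 ± 0.51), the coumarin hydroxylase S8H (AT3G12900, -3.53 ± 0.69), the P450 CYP82C4 (AT4G31940, -2.23 ± 0.53) and CA1 (-0.78 ± 0.15) (adjusted p at most 0.0015). Phosphate starvation markers did not pass as a list (1 of 12 rose and 1 fell, 1 up and 3 down adjusted over the list alone, median -0.84, camera adjusted p = 0.37). Their median was -0.13 when members without counts stood at their bound. In all 1422 genes rose and 1007 fell, 1421 and 968 in experiment A alone, 1030 and 512 in experiment B alone.

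In Col-0 at low Pi, MeJA was followed by lower counts of phosphate starvation genes. The markers had 11 of 12 members fall (11 adjusted over the list alone). The median was -2.13, with camera adjusted p = 4.1e-10. SPX3 (-3.54 ± 0.49) and PECP1 (-2.90 ± 0.49), the ribonuclease RNS1 (AT2G02990, -2.95 ± 0.54) and OCT1 (-4.81 ± 0.40) fell. AT4, chosen after its values were seen, went from 250.5 ± 109 CPM to 112 ± 68.3 CPM. Transport genes fell (1 of 9 rose and 6 fell, 1 up and 6 down adjusted over the list alone, median -0.78, camera adjusted p = 5.7e-06). PHT1;2 (-3.11 ± 0.28), PHO1;H1 (AT1G68740, -1.68 ± 0.20) and PHT1;9 (-1.45 ± 0.34) fell and the vacuolar transporter VPT1 (AT1G63010, 0.99 ± 0.14) rose. Lipid remodelling genes fell (8 of 10 fell, 8 adjusted over the list alone, median -1.28, camera adjusted p = 1.2e-07). They included MGD3 (-3.11 ± 0.53), NPC4 (-1.95 ± 0.28), GDPD1 (-1.60 ± 0.28) and MGD2 (-1.56 ± 0.30). Purple acid phosphatases had 2 of 6 members fall (5 adjusted over the list alone). The median was -0.53, with camera adjusted p = 0.0059 (adjusted p = 0.067 with an estimated correlation). PAP17 (-1.65 ± 0.42) and PAP12 (-0.54 ± 0.12) fell (adjusted p at most 0.0034). Jasmonate-responsive defence genes rose (16 of 19 rose, 16 adjusted over the list alone, median 5.38, camera adjusted p = 8.6e-28), among them PDF1.2 (10.26 ± 1.11), PDF1.2c (10.22 ± 1.08) and JAL23 (9.70 ± 1.04). Synthesis and signalling genes rose (32 of 37 rose, 33 adjusted over the list alone, median 2.56, camera adjusted p = 2.3e-67), among them JOX3 (8.55 ± 0.93), LOX2 (6.34 ± 0.60) and JAZ5 (6.07 ± 0.56). Aliphatic glucosinolate genes rose (17 of 19 rose, 19 adjusted over the list alone, median 1.51, camera adjusted p = 2.6e-32). So did indole glucosinolate (12 of 16 rose, 12 adjusted over the list alone, median 1.35, camera adjusted p = 3.8e-23) and camalexin genes (4 of 7 rose, 4 adjusted over the list alone, median 1.92, camera adjusted p = 4.8e-09). Examples were MYB76 (2.69 ± 0.35), BCAT4 (2.41 ± 0.27), IGMT1 (3.90 ± 0.44) and GSTF6 (2.24 ± 0.45). Anthocyanin genes had 12 of 18 members rise (12 adjusted over the list alone). The median was 2.03, with camera adjusted p = 3.2e-07 (adjusted p = 0.22 with an estimated correlation). Root hair genes did not pass (1 of 14 rose, 1 adjusted over the list alone, median -0.17, camera adjusted p = 0.84). Their mean was 0.02, above 0. The salicylic acid genes WRKY54 (AT2G40750, -2.57 ± 0.52) and PR2 (AT3G57260, -4.33 ± 0.97) fell and GRXC9 (AT1G28480, 3.86 ± 0.43) rose. PR2 changed by -5.15 in experiment A and 1.94 in experiment B. Altogether 1513 genes rose and 1094 fell, 1305 and 826 in experiment A alone, 1198 and 598 in experiment B alone, and 1315 and 1521 with scaling to total counts. The markers had medians of -2.44 in A and -0.96 in B.

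The MeJA response of Col-0 was then compared between low and high Pi. The lists of phosphate genes separated the responses. Lipid remodelling fell more at low Pi (0 of 10 passed, 8 adjusted over the list alone, median -1.21, camera adjusted p = 2.4e-18). So did phosphate starvation markers (1 of 12 fell, 2 adjusted over the list alone, median -1.15, camera adjusted p = 5.4e-08). Lower too were transport genes (0 of 9 passed, 1 adjusted over the list alone, median -0.61, camera adjusted p = 2.0e-05) and purple acid phosphatases (0 of 6 passed, 2 adjusted over the list alone, median -0.91, camera adjusted p = 2.0e-05, median -0.80 with a member without counts at its bound). The SPX-domain gene SPX2 (AT2G26660, -1.13 ± 0.22) passed alone (adjusted p = 0.041, and 0.089 with scaling to total counts). It stood at -1.21 in experiment A and -0.99 in B. That is 1 gene in edgeR, with 697 at an unadjusted p under 0.05 and 11 in DESeq2. Experiment A alone gave 338 and experiment B alone 0 calls. Genes that rose with MeJA at both supplies numbered 1100 (116 by chance) and 513 fell at both (59.3 by chance).

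**Figure D3:**
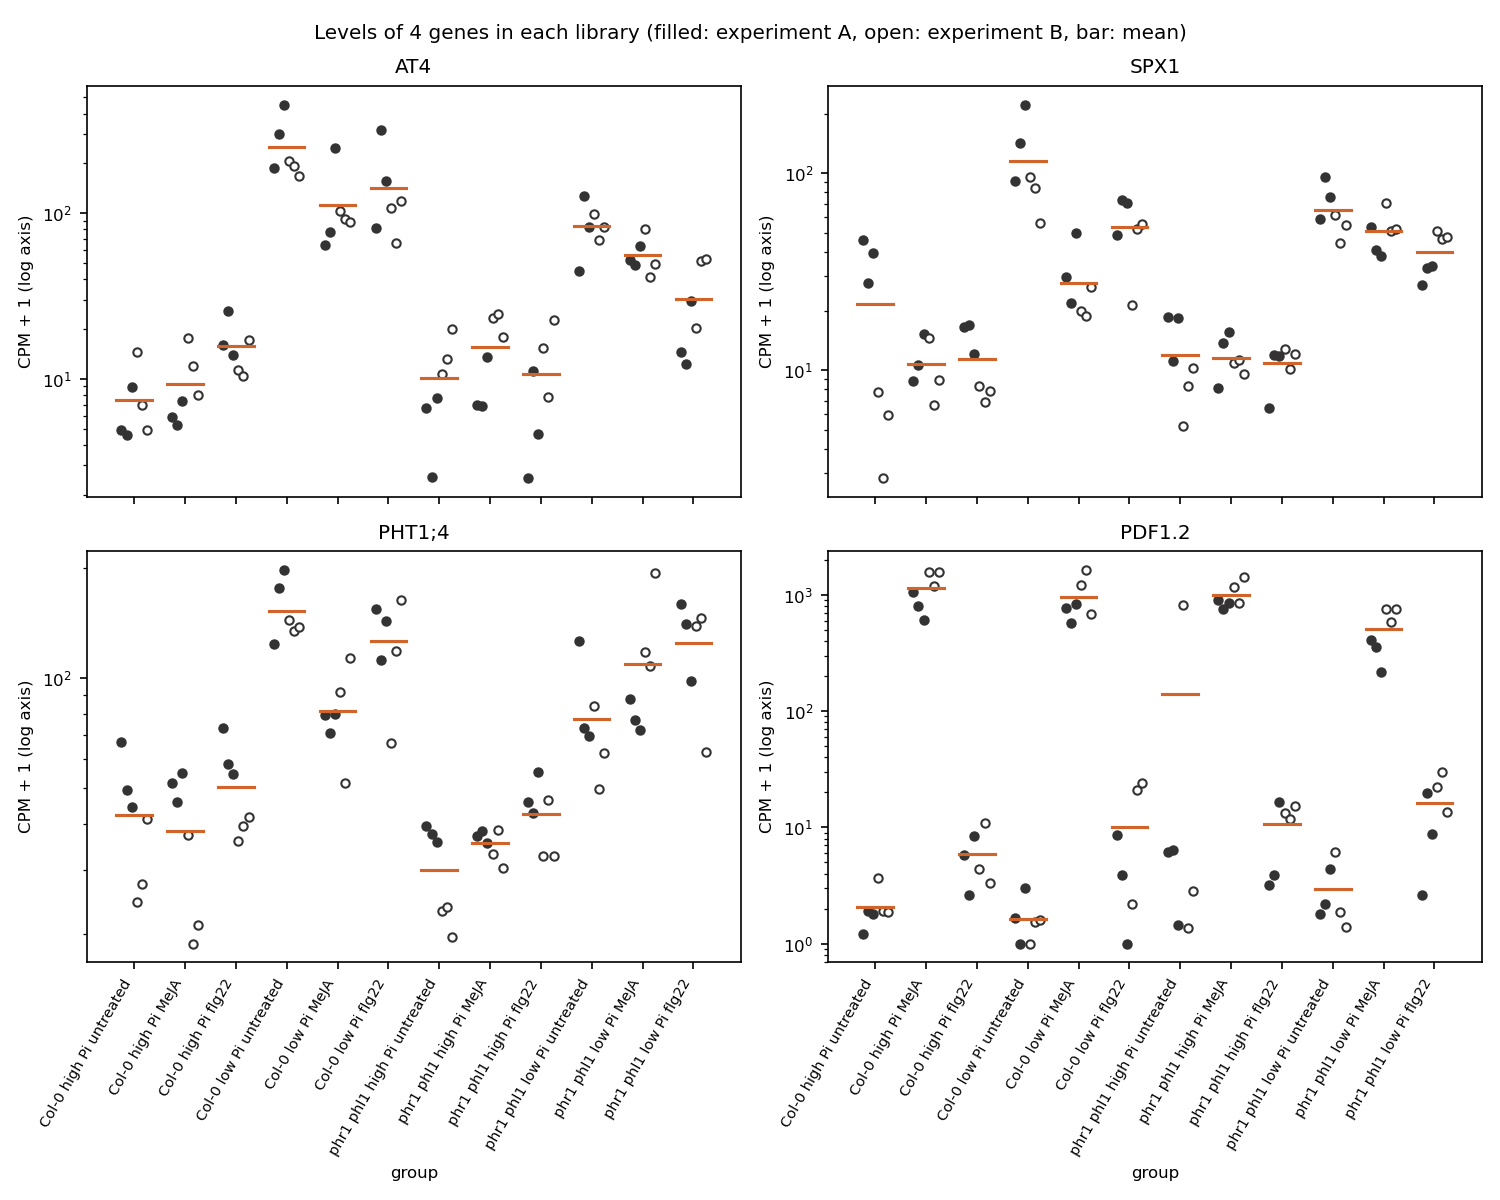
CPM plus 1 on a log axis of AT4, SPX1, PHT1;4 and PDF1.2 (panels) in the 6 libraries of each group, with filled points for experiment A, open points for B and a bar at the group mean. AT4 in Col-0 stands at a mean of 250.5 CPM at low Pi without treatment and 112 CPM with MeJA, and PDF1.2 reaches 818 CPM in the library labelled phr1 phl1 high Pi untreated B1. These 4 genes were chosen after their values were seen.

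In phr1 phl1, MeJA at low Pi raised jasmonate, glucosinolate and camalexin genes. Jasmonate-responsive defence genes rose (18 of 19 rose, 18 adjusted over the list alone, median 5.77, camera adjusted p = 6.3e-26). They included PDF1.2c (9.54 ± 1.12), VSP2 (8.79 ± 0.89) and JAL23 (8.90 ± 0.98) and the amine acetyltransferase NATA1 (AT2G39030, 9.74 ± 0.93). Synthesis and signalling genes rose as well (32 of 37 rose, 33 adjusted over the list alone, median 2.28, camera adjusted p = 1.3e-59), among them JOX3 (8.65 ± 0.92), AOC2 (5.90 ± 0.66), LOX2 (5.70 ± 0.58) and JAZ5 (5.52 ± 0.52). Aliphatic glucosinolate genes rose (17 of 19 rose, 18 adjusted over the list alone, median 1.52, camera adjusted p = 1.4e-31). So did indole glucosinolate (13 of 16 rose, 14 adjusted over the list alone, median 1.28, camera adjusted p = 2.5e-20) and camalexin genes (6 of 7 rose, 7 adjusted over the list alone, median 1.88, camera adjusted p = 4.1e-09). These included BCAT4 (2.73 ± 0.28), CYP79F2 (2.29 ± 0.24), GGP1 (2.05 ± 0.20) and PAD3 (1.91 ± 0.32) (adjusted p at most 4.1e-06). Anthocyanin genes had 12 of 18 members rise (13 adjusted over the list alone). The median was 1.88, with camera adjusted p = 5.7e-07 (adjusted p = 0.26 with an estimated correlation). Phosphate starvation markers had 0 of 12 members pass (0 adjusted over the list alone). The median was -0.12, with camera adjusted p = 0.83, and the mean was 0.02, above 0. In the transport list PHT1;2 (-2.84 ± 0.55) and PHO1;H1 (-1.31 ± 0.22) and the phosphate exporter PHO1 (AT3G23430, -0.68 ± 0.11) fell and VPT1 (1.195 ± 0.14) rose. PORA (-3.12 ± 0.63), GASA5 (-3.08 ± 0.41) and BGLU7 (AT3G62740, -2.79 ± 0.40) fell. So did the ferritins FER4 (AT2G40300, -0.998 ± 0.27) and FER3 (AT3G56090, -0.44 ± 0.16) (2 of 2 fell, 2 adjusted over the list alone, median -0.72, camera adjusted p = 0.057). Root hair genes had higher counts (10 of 14 rose, 11 adjusted over the list alone, median 0.79, camera adjusted p = 1.4e-05, adjusted p = 0.22 with an estimated correlation), and PRP1 (AT1G54970, 1.87 ± 0.32) and RSL4 (AT1G27740, 1.199 ± 0.30) rose. There were 1842 rising and 1285 falling genes, 1136 and 590 in experiment A alone, 1841 and 1059 in experiment B alone. Scaling to total counts gave 1450 and 2162 and moved the median of all genes to -0.11. Both genotypes shared 1189 rising (150 by chance) and 578 falling genes (75.6 by chance) at low Pi.

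The interaction at low Pi set the MeJA response of phr1 phl1 against that of Col-0. The phosphate lists were higher in the mutant. They were markers (0 of 12 passed, 10 adjusted over the list alone, median 2.27, camera adjusted p = 9.7e-21) and lipid remodelling (0 of 10 passed, 6 adjusted over the list alone, median 0.88, camera adjusted p = 5.0e-10). The others were transport (0 of 9 passed, 4 adjusted over the list alone, median 0.38, camera adjusted p = 4.8e-07) and purple acid phosphatases (0 of 6 passed, 4 adjusted over the list alone, median 0.75, camera adjusted p = 8.7e-06). Root hair genes were higher as well (0 of 14 passed, 7 adjusted over the list alone, median 0.80, camera adjusted p = 1.8e-14). The putative chitinase gene CHI (AT2G43570, 3.30 ± 0.55) and the transporter gene ABCG40 (AT1G15520, 2.78 ± 0.47) passed alone, both adjusted p = 0.0016. Those were the 2 calls of edgeR, with 871 genes at an unadjusted p under 0.05 and 7 in DESeq2. There were 3 in experiment A alone and 3 in B alone.

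At high Pi, MeJA in phr1 phl1 raised jasmonate defence genes (16 of 19 rose, 17 adjusted over the list alone, median 2.96, camera adjusted p = 1.8e-21). The median was 5.78 without the doubted library. PDF1.2 (3.44 ± 0.73), NATA1 (3.92 ± 0.57) and JOX3 (3.55 ± 0.66) rose, and by 8.16, 7.80 and 8.79 without it. Jasmonate synthesis (30 of 37 rose, 31 adjusted over the list alone, median 1.71, camera adjusted p = 1.3e-47) and aliphatic glucosinolate genes (17 of 19 rose, 17 adjusted over the list alone, median 1.02, camera adjusted p = 3.0e-20) rose. So did indole glucosinolate (12 of 16 rose, 13 adjusted over the list alone, median 1.21, camera adjusted p = 1.5e-23) and camalexin genes (6 of 7 rose, 6 adjusted over the list alone, median 1.61, camera adjusted p = 4.9e-09). Examples were AOS (AT5G42650, 3.24 ± 0.28), BCAT4 (1.69 ± 0.26), ASA1 (1.70 ± 0.22) and PAD3 (1.90 ± 0.38) (adjusted p at most 3.8e-04). The methyltransferase FAMT (AT3G44860, 3.94 ± 0.41) rose. GASA5 (-3.01 ± 0.37) and BGLU7 (-2.65 ± 0.35) fell. Phosphate starvation markers did not pass (1 of 12 rose, 1 adjusted over the list alone, median 0.22, camera adjusted p = 0.54). IPS1 (2.21 ± 0.55) rose. The counts were 1560 up and 1150 down, 1854 and 1554 without that library, and 1229 and 1852 with it and scaling to total counts. Experiment A alone gave 1699 and 1139. Experiment B alone gave 649 and 354, or 1414 and 758 without it. Against Col-0 at high Pi, 30 genes responded less in the mutant and 1 more. PDF1.2 (-6.66 ± 1.27), JAL23 (-6.20 ± 1.26) and JOX3 (-5.84 ± 1.29) were lower. Without that library 0 passed in edgeR at the adjusted threshold. The changes of these 3 genes were -1.85, -0.89 and -0.54 (adjusted p = 1 for each). The unadjusted count with it was 937, DESeq2 called 59, and experiments A and B alone 9 and 10. The defence list had 6 of 19 members fall (14 adjusted over the list alone). The median was -2.44, with camera adjusted p = 2.2e-13 (adjusted p = 0.12 with an estimated correlation). Without that library it had 0 of 19 members pass (0 adjusted over the list alone). The median was -0.31, with camera adjusted p = 0.015 (adjusted p = 0.71 with an estimated correlation).

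The response to flg22 was measured against no treatment. In Col-0 at high Pi, the indole glucosinolate genes IGMT2 (AT1G21120, 2.003 ± 0.37) and CYP81F2 (AT5G57220, 1.78 ± 0.31) and their regulator MYB51 (AT1G18570, 1.29 ± 0.25) rose. So did the peroxidases PER4 (AT1G14540, 1.47 ± 0.30), PER5 (AT1G14550, 1.37 ± 0.36) and PRX52 (AT5G05340, 3.83 ± 0.998) (adjusted p at most 0.045). The oxidase gene AT1G26380 (2.75 ± 0.57), the trypsin inhibitor KTI1 (AT1G73260, 2.40 ± 0.55), the wall enzyme XTH26 (AT4G28850, 2.27 ± 0.53) and the root hair proline-rich protein PRP1 (2.22 ± 0.32) rose. The transporter gene AT2G04050 (-2.71 ± 0.59) and BT1 (AT5G63160, -1.60 ± 0.32) fell. So did G3PP1 (AT3G47420, -0.95 ± 0.18) (adjusted p at most 0.019). Pattern-triggered immunity genes had 2 of 29 members rise (10 adjusted over the list alone). The median was 0.45, with camera adjusted p = 9.3e-08 (adjusted p = 0.094 with an estimated correlation). Indole glucosinolate synthesis had 3 of 16 members rise (3 up and 1 down adjusted over the list alone). The median was 0.12, with camera adjusted p = 2.0e-04 (adjusted p = 0.35 with an estimated correlation). Root hair genes had 2 of 14 members rise (7 adjusted over the list alone). The median was 0.52, with camera adjusted p = 2.1e-10 (adjusted p = 0.094 with an estimated correlation). The counts were 96 up and 49 down, 969 and 690 in experiment A alone, 29 and 9 in experiment B alone. They were 161 and 79 in DESeq2, and 159 and 33 with scaling to total counts.

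In Col-0 at low Pi, flg22 was followed by higher pattern-triggered immunity genes (5 of 29 rose, 12 adjusted over the list alone, median 0.57, camera adjusted p = 2.5e-10). Among them were the receptor kinase FRK1 (AT2G19190, 3.46 ± 0.75), MLO12 (AT2G39200, 1.51 ± 0.33) and the transporter PEN3 (AT1G59870, 0.93 ± 0.20). Camalexin (2 of 7 rose, 3 adjusted over the list alone, median 0.66, camera adjusted p = 5.6e-05) and senescence genes (1 of 11 rose, 4 adjusted over the list alone, median 0.30, camera adjusted p = 3.9e-04) rose as lists. They included CYP71A12 (3.19 ± 0.57), GSTF6 (2.66 ± 0.45) and ORE1 (AT5G39610, 0.98 ± 0.29). Indole glucosinolate genes had 6 of 16 members rise and 1 fall (7 up and 1 down adjusted over the list alone). The median was 0.29, with camera adjusted p = 3.2e-05 (adjusted p = 0.087 with an estimated correlation). IGMT2 (2.62 ± 0.36), IGMT1 (2.13 ± 0.45), CYP81F2 (1.64 ± 0.32) and MYB51 (1.25 ± 0.23) rose (adjusted p at most 0.036). Phosphate starvation markers fell (6 of 12 fell, 1 up and 10 down adjusted over the list alone, median -1.01, camera adjusted p = 2.6e-06), SPX1 (-1.09 ± 0.30) among them. So did transport (2 of 9 fell, 4 adjusted over the list alone, median -0.27, camera adjusted p = 5.6e-05) and lipid remodelling genes (5 of 10 fell, 7 adjusted over the list alone, median -0.75, camera adjusted p = 2.6e-06). Examples were PHT1;2 (-1.67 ± 0.25), PHF1 (-0.82 ± 0.16), MGD3 (-1.76 ± 0.46), NPC4 (-1.21 ± 0.26) and SQD2 (AT5G01220, -1.02 ± 0.25) (adjusted p at most 0.024). Endodermis and root tip genes fell (4 of 12 fell, 5 adjusted over the list alone, median -0.38, camera adjusted p = 5.6e-05), among them CASP4 (-1.01 ± 0.28) and CASP2 (AT3G11550, -0.81 ± 0.22). Cell division genes fell (2 of 12 fell, 3 adjusted over the list alone, median -0.27, camera adjusted p = 1.6e-04), among them the kinases AUR1 (AT4G32830, -0.72 ± 0.14) and CDKB1;1 (AT3G54180, -0.61 ± 0.17). Root hair genes had 1 of 14 members rise and 2 fall (1 up and 3 down adjusted over the list alone). The median was -0.41, with camera adjusted p = 3.9e-04 (adjusted p = 0.25 with an estimated correlation). RHD6 (AT1G66470, -1.35 ± 0.27) and EXPA18 (-0.76 ± 0.23) fell and PRP1 (1.29 ± 0.29) rose. PR2 (-4.04 ± 0.95) and PR5 (AT1G75040, -1.35 ± 0.39) fell, with PR2 at -6.01 in experiment A and 2.82 in experiment B. The iron deficiency list did not pass (2 of 18 rose and 5 fell, 7 up and 6 down adjusted over the list alone, median 0.56, camera adjusted p = 0.43), and its median lay above 0 while the test pointed down. In all 451 genes rose and 256 fell, 521 and 392 in experiment A alone, 161 and 43 in experiment B alone, and 364 and 320 with scaling to total counts. Between low and high Pi, the flg22 response of root hair genes was lower at low Pi (0 of 14 passed, 13 adjusted over the list alone, median -0.96, camera adjusted p = 1.7e-20). Phosphate starvation markers had 0 of 12 members pass (1 adjusted over the list alone). The median was -0.42, with camera adjusted p = 4.0e-04 (adjusted p = 0.17 with an estimated correlation). The nucleotide kinase PYR6 (AT5G26667, -0.62 ± 0.12) was the 1 gene past the threshold in edgeR (adjusted p = 0.031). There were 1197 at an unadjusted p under 0.05, 3 in DESeq2, 344 in experiment A alone and 11 in B alone.

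In phr1 phl1 at low Pi, pattern-triggered immunity genes rose with flg22 (9 of 29 rose, 13 adjusted over the list alone, median 0.41, camera adjusted p = 5.1e-10). Examples were the danger peptide PROPEP3 (AT5G64905, 2.39 ± 0.49) and PER5 (1.89 ± 0.39) and PER4 (1.31 ± 0.31). PRX52 (3.94 ± 0.70), KTI1 (3.43 ± 0.53) and XTH26 (2.96 ± 0.55) rose. So did the indole enzyme CYP81F2 (1.59 ± 0.31) and the regulator of senescence ORE1 (1.57 ± 0.29) (adjusted p at most 0.0060). Among defence genes of the jasmonate list (3 of 19 rose, 5 adjusted over the list alone, median 0.68, camera adjusted p = 0.027, adjusted p = 0.74 with an estimated correlation, median 0.57 with members without counts at their bound), PDF1.3 (3.79 ± 1.01) and PR4 (AT3G04720, 1.75 ± 0.35) rose. The oxidase AOX1D (AT1G32350, -2.89 ± 0.46), BIP3 (-4.42 ± 0.76) and AT2G04050 (-2.71 ± 0.43) and AT4 (-1.55 ± 0.41) fell and PHT1;1 (1.12 ± 0.17) rose (adjusted p at most 0.021). Phosphate starvation markers had 3 of 12 members fall (3 up and 3 down adjusted over the list alone). The median was -0.43, with camera adjusted p = 0.36. The counts were 366 up and 183 down, 890 and 587 in experiment A alone, 76 and 21 in experiment B alone, and 207 and 318 with scaling to total counts. Both genotypes shared 166 rising (8.88 by chance) and 33 falling genes (2.52 by chance) at low Pi. Against Col-0, the flg22 response of root hair genes (0 of 14 passed, 10 adjusted over the list alone, median 0.92, camera adjusted p = 1.9e-21) and transport genes (1 of 9 rose, 4 adjusted over the list alone, median 0.61, camera adjusted p = 1.4e-06) was higher in the mutant. That of camalexin genes was lower (0 of 7 passed, 3 adjusted over the list alone, median -1.06, camera adjusted p = 1.9e-07). PHT1;1 (1.22 ± 0.23) and AT5G13210 (-2.38 ± 0.46) were the 2 genes past the threshold in edgeR (adjusted p = 0.026 and 0.026). There were 768 at an unadjusted p under 0.05, 11 in DESeq2, 20 in experiment A alone and 0 in B alone.

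In phr1 phl1 at high Pi, flg22 raised pattern-triggered immunity genes (8 of 29 rose, 11 adjusted over the list alone, median 0.38, camera adjusted p = 1.1e-11). PER5 (3.19 ± 0.40), FRK1 (2.83 ± 0.62), PER4 (2.38 ± 0.31) and PROPEP3 (2.02 ± 0.46) rose. Without the doubted library they rose by 3.07, 2.77, 2.28 and 2.02. IGMT2 (2.93 ± 0.38), CYP81F2 (1.74 ± 0.31), MYB51 (1.34 ± 0.25) and CYP71A12 (2.94 ± 0.51) rose. So did the P450 CYP82C2 (AT4G31970, 3.95 ± 0.70), AT1G26380 (3.39 ± 0.57) and the salicylic acid regulators SARD1 (AT1G73805, 2.49 ± 0.67) and CBP60g (AT5G26920, 1.33 ± 0.31) (adjusted p at most 0.015). Salicylic acid genes had 5 of 22 members rise and 1 fall (5 up and 1 down adjusted over the list alone). The median was 0.42, with camera adjusted p = 3.8e-04 (adjusted p = 0.58 with an estimated correlation). The median was 0.70 without that library. FIT (AT2G28160, -0.67 ± 0.14), a regulator of iron uptake, and G3PP1 (-0.82 ± 0.18) fell. With that library jasmonate defence genes had 10 of 19 members fall (13 adjusted over the list alone). The median was -3.00, with camera adjusted p = 0.032 (adjusted p = 0.58 with an estimated correlation). Without it they had 3 of 19 members rise (3 up and 1 down adjusted over the list alone). The median was 0.11, with camera adjusted p = 0.19. VSP2 (-5.75 ± 1.001) and JOX3 (-4.80 ± 0.93) fell with it, and changed by -0.86 and 0.43 (adjusted p = 0.56 and 0.81) without it. The counts were 579 up and 499 down, 593 and 271 without it, and 435 and 575 with it and scaling to total counts. Experiment A alone gave 993 and 596. Experiment B alone gave 251 and 268, or 143 and 61 without it. Against Col-0 at high Pi, edgeR called 0 genes, with 1127 at an unadjusted p under 0.05, 54 in DESeq2, 16 in experiment A alone and 1 in B alone. The jasmonate synthesis list had 0 of 37 members pass (17 adjusted over the list alone). The median was -0.68, with camera adjusted p = 5.3e-10 (adjusted p = 0.43 with an estimated correlation). Without that library it had 0 of 37 members pass (0 adjusted over the list alone). The median was -0.14, with camera adjusted p = 0.030 (adjusted p = 0.54 with an estimated correlation).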

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

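The tests of the library labelled phr1 phl1 high Pi untreated B1, of the spread and the response of experiment B and of the MeJA response at low Pi were chosen after the result was seen, as were the counts of other splits for low Pi in each genotype and for the genotypes at each Pi supply and those without that library. The depth test and the other split counts were chosen before.

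The doubted library had a mean of 6.18 log2 CPM over the jasmonate-responsive defence genes. The other 5 libraries of its group had 1.34 to 2.08. An exchange with another of the 72 libraries is argued against. By the ratio of PHL1 to PHR1 and the MeJA axis, 0 of the other 71 libraries went against their label for genotype or MeJA. Labels for flg22 and Pi supply were not checked this way. Its log2 ratio of PHL1 to PHR1 of -1.76 lay within the range of Col-0 (-3.29 to -1.67), as a Col-0 MeJA library under a wrong label would give. Its position of 0.925 on the MeJA axis lay between the other libraries without MeJA (at most 0.164) and those with it (at least 0.957), as a mixture with a small share of another library could give. A wrong label and a mixture both stay open.

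Low Pi changed 6390 genes in experiment A and 84 in experiment B in untreated Col-0, and 58.5% of the 6295 genes called in A and measured in B had the same sign in B. Lower depth in B is argued against, since experiment A thinned to the depth of B still gave at least 5675 calls in 10 draws. A larger spread in B at an equal effect (biological coefficient of variation 0.153, against 0.113 in A) is argued against as the whole cause, since the effect itself differed for 2767 genes in edgeR. Whether the plants of B responded less cannot be told apart from an equal response by the phosphate genes, whose median in B was 0.742 times that in A (95% interval 0.586 to 1.29 over 36 genes). The growth conditions of each experiment were not analysed here.

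The phosphate starvation markers fell under MeJA at low Pi in Col-0 (median -2.13). A few genes taking most counts are argued against, since scaling to total counts gave medians of -2.18 (markers) and -0.06 (all genes). A lower share of root tissue alone is argued against by the root endodermis median of -0.20 (upper quartile of markers -1.15). A smaller loss stays open. Root hair genes (-0.17) cannot tell, as they rose under MeJA in phr1 phl1. A candidate explanation, found and tested on the same data, is a response that needs PHR1 and PHL1. In phr1 phl1 the markers had a median of -0.12 under MeJA, although low Pi had raised them by 1.92 (1.74 without the doubted library). Their interaction of MeJA with genotype at low Pi had a median of 2.27. In the transport list PHT1;2 and PHO1;H1 went against this explanation, falling in phr1 phl1 (-2.84 and -1.31) as in Col-0 (-3.11 and -1.68). That list's interaction had a median of 0.38.

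Of 60 tests (12 groups of 6 libraries by 5 measures), 3 held a library far from the rest, and chance alone gives about 1 in 20. The other 2 were PHL1 at 102 CPM in the library labelled phr1 phl1 high Pi MeJA B3, against 30.9 to 51.8 CPM in the other 5, and PHL1 at 20.3 CPM in the library labelled Col-0 low Pi MeJA A3, against 9.77 to 13.7 CPM.

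Several effects differed between groups in a test of the difference itself. The genotypes differed in the low Pi effect of 159 genes, and in that of root hair genes with a median of -1.21 (adjusted p = 0.0050, camera with an estimated correlation, here and below). The MeJA effect in Col-0 differed between low and high Pi for 1 gene and for the markers (-1.15, adjusted p = 0.020), transport (-0.61, 0.020), lipid remodelling (-1.21, 2.1e-04) and purple acid phosphatase lists (-0.91, 0.0092). Between the genotypes it differed for 31 genes at high Pi, and 0 without the library labelled phr1 phl1 high Pi untreated B1 in edgeR (937 at an unadjusted p under 0.05 with it, 59 in DESeq2). At low Pi it differed for 2 genes and for the markers (2.27, 1.3e-04), transport (0.38, 0.0048), lipid remodelling (0.88, 0.0048), purple acid phosphatases (0.75, 0.0048) and root hair genes (0.80, 0.010). The flg22 effect in Col-0 differed between low and high Pi for 1 gene and for root hair genes (-0.96, 0.0072). Between the genotypes at low Pi it differed for 2 genes and for transport (0.61, 0.0068), camalexin (-1.06, 0.0051) and root hair genes (0.92, 0.0051).

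Libraries were regrouped within experiments, in a model of the groups compared only, so the real counts differ from the whole model. For the 12 comparisons of 2 groups with all libraries chance can be excluded, with the real grouping alone (1 of 100) at its count. Real and highest other counts were 1460 and 1310 for low Pi in Col-0, 1435 and 837 in phr1 phl1, 72 and 9 for the genotypes at high Pi and 778 and 383 at low Pi. For MeJA they were 2485 and 138 in Col-0 at high Pi, 2521 and 7 at low Pi, 2811 and 1272 in phr1 phl1 at high Pi and 3806 and 53 at low Pi. For flg22 they were 131 and 89, 874 and 121, 1248 and 3, and 1031 and 2 in the same order. Without the doubted library the real grouping still stood alone in phr1 phl1 for low Pi (2049, highest other 1524). It also did for MeJA (3777 and 2321) and flg22 (1653 and 504) at high Pi. For the genotypes at high Pi 2 of 100 groupings reached the 105 of the real one, but the other called 332, so chance is not taken as excluded. For the interactions 70 groupings were counted. For low Pi with genotype with all libraries the real grouping alone reached its count (83, highest other 0), which argues against chance. Without that library chance is not argued against (87, reached by 2 groupings, highest other 89). For MeJA with genotype at low Pi 2 groupings reached the 1 gene of the real one, but the other called 22 and leaving out replicate A3 or B1 gave 0, so that count is not taken to exclude chance. Chance cannot be excluded for flg22 with genotype at low Pi (3 genes, reached by 4 groupings, highest other 159). A real count of 0 in edgeR is reached by all 70 groupings, so that count tests nothing for MeJA with Pi (highest other 9), MeJA with genotype at high Pi (130), flg22 with Pi (279) and flg22 with genotype at high Pi (0). In the model of all groups these 4 interactions had 697, 937, 1197 and 1127 genes at an unadjusted p under 0.05, and DESeq2 called 11, 59, 3 and 54. Groupings that call many times the real count point to a structure of the samples, whose source was not tested.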

How the results depend on the processing

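Leaving out the doubted library, alone or with experiment B fitted alone, was chosen after the data were examined, and the other alternatives before. Counts of genes called are given where they moved by over 1.5 times, in a fixed order. The order is low Pi in Col-0 and phr1 phl1, the genotypes at high and low Pi, MeJA and then flg22 each in Col-0 at high and low Pi and in phr1 phl1 at high and low Pi, and the interactions. All counts are edgeR's unless DESeq2 is named, and the cause was not tested except where fewer samples or a stricter rule give it.

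Of 19 counts, 19 stayed within 1.5 times with the size factors of DESeq2 and with a mean of at least 10 counts, and 18 with total counts, where MeJA with Pi gave 0. At an adjusted p below 0.01 and a fold of at least 1.5, the 12 comparisons of groups gave 919, 859, 91, 328, 1265, 1382, 1303, 1503, 38, 226, 441 and 195. Low Pi with genotype gave 50, and MeJA with Pi, MeJA with genotype at high Pi, flg22 with Pi and flg22 with genotype at low Pi 0 each. DESeq2 gave 240 for flg22 in Col-0 at high Pi and 277 for low Pi with genotype. It gave 11, 59 and 7 for the interactions of MeJA with Pi and with genotype at high and low Pi, and 3, 54 and 11 for those of flg22. Without a filter, flg22 in Col-0 at high Pi gave 93, MeJA with genotype at high Pi 18, and MeJA and flg22 with Pi 0 each. Without the experiment term flg22 gave 50 in Col-0 at high Pi and 360 in phr1 phl1 at low Pi, and MeJA with Pi, flg22 with Pi and flg22 with genotype at low Pi 0 each. With only the groups compared, low Pi gave 1460 and 1435, the genotypes at high Pi 72, and flg22 in phr1 phl1 at low Pi 1031. The interactions gave 83 for low Pi with genotype, 1 for MeJA with genotype at low Pi, and 0 for MeJA with Pi, MeJA with genotype at high Pi and flg22 with Pi.

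Experiment A alone gave 6390 and 5228 for low Pi, 1057 for the genotypes at low Pi, 1726 for MeJA in phr1 phl1 at low Pi, and 1659 and 1477 for flg22 in Col-0 at high and phr1 phl1 at low Pi. Its interactions gave 447 for low Pi with genotype, 338 and 9 for MeJA with Pi and with genotype at high Pi, and 344, 16 and 20 for the interactions of flg22. Experiment B alone gave 84 and 429 for low Pi, 96 for the genotypes at low Pi, 1542 and 1003 for MeJA in Col-0 and phr1 phl1 at high Pi, and 38, 204, 519 and 97 for flg22. It gave 1, 0, 10, 11, 1 and 0 for the interactions other than MeJA with genotype at low Pi. Without the doubted library it gave 105, 135, 5 and 112 for low Pi and the genotypes, 50, 321, 204 and 137 for flg22, and 0, 0, 6, 4, 19, 1 and 0 for the interactions. Over all libraries but that one, the genotypes at high Pi gave 12, low Pi with genotype 97, MeJA with Pi 2, MeJA with genotype at high Pi 0 and flg22 with Pi 2.

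Leaving out each replicate number in turn, 12 libraries at a time, gave 770 to 3567 and 942 to 2750 for low Pi, 16 to 229 and 314 to 643 for the genotypes, 1821 to 2248, 2058 to 2329, 1942 to 3012 and 2301 to 2914 for MeJA. It gave 42 to 276, 312 to 752, 637 to 906 and 206 to 629 for flg22, and for the interactions 39 to 120 for low Pi with genotype, 0 to 1, 0 to 10 and 0 to 4 with MeJA, and 0 to 3, 0 to 0 and 0 to 3 with flg22. The replicate numbers did not pair the samples, with a mean correlation of -0.0015 between same-numbered libraries, 63 of 396 pairs over 0.1, and 21 of 72 libraries closest to their own number. With that number as a block the call count for MeJA with genotype at high Pi was 0 and the other 18 counts stayed within 1.5 times.

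Changes of single genes named in the text were refitted too, 286 of them giving 3380 values. Direction and call held in 3001, the call was lost in 361 and the direction turned in 18. For 112 list results with 1008 values these were 927, 71 and 5, with 5 calls gained.

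Fits of experiment B alone turned PR2 to 1.94 under MeJA and 2.82 under flg22 at low Pi in Col-0, and without the doubted library to 1.94 and 2.81. Experiment A alone turned JOX3 under flg22 in phr1 phl1 at high Pi to 1.03 (0.43 without the doubted library) and PDF1.2c between the genotypes at high Pi to -0.13. In experiment B without the doubted library, AOC2, JOX3, PDF1.2, PDF1.2c and PDF1.3 turned to -0.15, -0.089, -0.30, -0.42 and -0.023 between the genotypes at high Pi. There AOC2 turned to 1.66 in low Pi with genotype, CYP79F1, CYP79F2 and PDF1.2 to 0.30, 0.051 and 0.91 under low Pi in phr1 phl1, and JAL23 and JOX3 to 0.48 and 0.71 in MeJA with genotype at high Pi. The direction of the list of aliphatic glucosinolates under low Pi in Col-0 turned in experiment B (camera adjusted p = 0.24) and that of lipid remodelling between the genotypes at low Pi too (0.0020). That of jasmonate defence genes turned under flg22 in phr1 phl1 at high Pi (0.75 in experiment A, 0.19 without the doubted library) and under low Pi in phr1 phl1 (0.90 without it). Depth limits genes with few counts, such as IPS1, which had no counts in Col-0 high Pi MeJA, the shallowest group with at most 2403150 counts per library.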

Other observations

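The gene lists and the rule for the members named were fixed before the data were examined, and which lists to describe was chosen after the result was seen. Under MeJA at low Pi in phr1 phl1, immune genes outside the jasmonate pathway changed as well. Pattern-triggered immunity genes had 11 of 29 members rise and 2 fall (13 up and 4 down adjusted over the list alone). The median was 0.45, with camera adjusted p = 3.2e-04 (adjusted p = 0.22 with an estimated correlation). PROPEP3 (2.46 ± 0.49) and the zinc finger regulator ZAT10 (AT1G27730, 1.90 ± 0.30) rose, while PHI1 (AT1G35140, -1.38 ± 0.44) fell. Salicylic acid genes had 7 of 22 members rise (7 adjusted over the list alone). The median was 0.51, with camera adjusted p = 0.0020 (adjusted p = 0.38 with an estimated correlation). Medians were -0.17 in experiment A and 1.23 in experiment B. The salicylic acid exporter EDS5 (AT4G39030, 2.13 ± 0.26), the glucosyltransferase UGT76B1 (AT3G11340, 1.89 ± 0.21) and the glutaredoxin GRXC9 (3.25 ± 0.39) rose (edgeR adjusted p at most 0.021). The difference of these lists from Col-0 had adjusted p = 0.056 and 0.36 with an estimated correlation.

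Some photosynthesis genes fell under MeJA at low Pi. In Col-0 the list had 6 of 28 members fall (6 adjusted over the list alone). The median was -0.23, with camera adjusted p = 3.1e-05 (adjusted p = 0.38 with an estimated correlation). The carboxylase subunit RBCS2B (AT5G38420, -0.49 ± 0.14) fell there, as did CA1 (-0.66 ± 0.15) and RCA (-0.46 ± 0.14). In phr1 phl1 it had 6 of 28 members fall (6 adjusted over the list alone). The median was -0.23, with camera adjusted p = 1.4e-04 (adjusted p = 0.47 with an estimated correlation). Medians were 0.01 in experiment A and -0.46 in experiment B. Without treatment, iron genes fell in phr1 phl1 at low Pi, among them the iron transporter IRT1 (AT4G19690, -0.85 ± 0.29) and its regulator FIT (-0.44 ± 0.14) (adjusted p = 0.041 and 0.027). Without the doubted library these changes were -0.93 and -0.46 (adjusted p = 0.031 and 0.030). The iron deficiency list had 4 of 18 members fall (9 adjusted over the list alone). The median was -1.13, with camera adjusted p = 1.0e-05 (adjusted p = 0.18 with an estimated correlation). Without that library 8 members fell.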
